A study of Mus musculus with 2 samples.

How the data were processed

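H3K9ac was measured by ChIP-seq in whole lung of newborn mice (postnatal day 0) in 2 biological replicates, which form the only group. Replicate 1 was a pool of 15 mice and replicate 2 a pool of unstated size, with fragments of 300 to 500 bp per the labels. No read counts or alignments were in the files, so depth and the precision it gives are unknown, and no tissue, age or treatment could be compared.

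The deposited peak lists, on mm10, hold 1 list per replicate, 1 called on both replicates together and 1 of replicated peaks. The fold enrichment of each peak over its background, a ratio, was computed by the authors before deposit. The −log10 p and −log10 q of each peak were also computed by the authors, and no deposited −log10 p was under 2.00. Aligner, peak caller and their versions, and the rule for keeping a replicated peak, are not given in the sources used here. Values in each list are relative to that list's own background, so they served mainly to rank peaks within a list.

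Peaks on the 21 placed chromosomes were analysed, and transcript starts and gene types came from the GENCODE mouse annotation, release M21. A peak recurred when at least 0.5 of its length was covered by the other replicate's peaks, beside 100 shuffles within chromosomes. Correlations used pairs of peaks with the largest mutual overlap. Promoters were 1000 bp either side of any annotated transcript start, and a gene was marked when a replicated peak overlapped one. Promoters were classed by observed over expected CpG within 500 bp of the gene's 5′ end, as CpG-poor under 0.4, CpG-rich over 0.6 and intermediate between. A gene with several starts can carry its peak at a start other than the classed one. CpG classes and CpG-matched lists therefore describe the 5′ end and not always the marked promoter. The strength of a promoter was the geometric mean, over both replicates, of the fold enrichment of its strongest peak. Domains joined replicated peaks at most 500 bp apart. Of 21938 protein-coding gene identifiers, 27 symbols had several, of which the first identifier was kept, which left 21911 genes.

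The 38 gene lists comprised 12 of lung cell types, 11 of cell types of other tissues or blood and 15 gene groups, written from general knowledge. Of 528 members asked for, 527 matched a gene, 1 of them by another name (Dnai1 as Dnaic1), and the haemoglobin-stabilising gene Ahsp did not match. Foxf1 was in 2 lung lists, Lpcat1, Aqp5, Mfap4, Pdgfra, Fgfr4 and Fgf10 were each in a lung list and a gene group, and 0 genes were in both a lung and another cell type list. How many members of the other cell type lists the newborn lung expresses was not measured. Non-coding members (H19, Meg3, Kcnq1ot1, Xist, Tsix) were not tested.

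Marked members were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 38 lists and a threshold of 0.05. Promoter strength was placed among 10000 random lists of marked genes of the same CpG classes, and the ratio between replicates among 10000 lists matched on strength, with percentiles of 2.5 and 97.5 as limits. Distal peaks lay over 5000 bp from any transcript start, and those within 50000 bp of a list's starts were compared with 10000 random lists by a two-sided permutation test. Consensus sequences of 22 transcription factors were searched on both strands within 500 bp of distal peak midpoints and in windows 10000 bp away that overlap no pooled peak, matched 1 to 1 in GC bins of 2%. Of 2113 distal peaks 1610 found a match, with a mean GC content of 49.1% in both sets.

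Genes were named by rule, namely the 20 strongest promoters and 15 widest domains. For each list the rule named up to 4 strongest members and the first 3 members without a replicated peak. It also named the 10 strongest distal peaks and the 5 strongest promoters of each replicate without a promoter peak in the other. The lists, tests, naming rule and most alternatives were fixed before the data were examined. Alternatives covered a −log10 q of at least 5, the strongest 50% of peaks, other overlaps, windows, transcript starts and distances, the pooled list, each replicate alone, CpG-matched lists and unmatched controls. Leaving out distal peaks near RefSeq starts, and keeping only peaks that overlap both replicates by 50%, were added after the data had been examined. No paired analysis was possible because the only 2 samples belong to 1 group.

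Tests were checked on simulated data. A planted recurrence of 40.0% over 42566 peaks was recovered as 40.3%. Recurring peaks were copied at the same coordinates, so this checked the counting and not how the overlap rule treats shifted or split peaks. Lists of 14 members with a planted odds ratio of 10 were called in 69% of cases, against 2% of unchanged lists with an unadjusted p under 0.05. The random-list comparison was checked on continuous simulated values in place of distal peak counts. Shifted lists were found in 75% of cases, against 4% of unchanged lists. Real distal counts are far sparser, with a mean of 0.170 in random lists of 12 genes, so this rate does not carry over to them. The 12 liver genes, with 0 distal peaks, had an unadjusted p of 0.407 by permutation, so for such small lists a decrease could not be detected. A planted sequence was found in 30.9% of 1872 windows and in 0.481% of controls. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, with a seed of 1 for the main random draws.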

Results

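Acetylation of lysine 9 on histone H3 (H3K9ac), a chromatin mark found at active promoters and enhancers, was mapped by ChIP-seq in the lungs of newborn mice at postnatal day 0. The series held 1 group of 2 biological replicates and no other tissue, age or treatment. Replicate 1 came from the pooled lungs of 15 mice and replicate 2 from pooled mice whose number the labels do not give, and both pools held males and females. Each replicate had its own peak list, with 42571 peaks in replicate 1 and 42692 in replicate 2. A list called on both replicates together held 45147 peaks, and a list of replicated peaks held 19971. The peak lists carry no read counts, so the depth of each library was unknown and a promoter without a peak is one where no peak was called, not one shown to lack the mark. All coordinates are on mm10. The fold enrichment of a peak is the authors' value. With 1 group, tests across genes or windows describe these 2 libraries, and intervals on shares are 95% Wilson intervals that cover counting error only.

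The first comparison asked how far the peaks of one replicate recurred in the other. The strongest H3K9ac peaks recurred almost without exception, and the weakest recurred rarely. Of the 5000 strongest peaks of replicate 1 by −log10 p, 99.8% had at least 50% of their length covered by peaks of replicate 2, and the share was 99.9% in the opposite direction. Among peaks ranked from 15001 to 20000 the shares were 36.7% and 37.4%, and beyond rank 40000 they were 9.70% and 9.41%. Over whole lists, 44.1% of replicate 1 peaks (interval 43.6 to 44.5) and 44.6% of replicate 2 peaks (interval 44.2 to 45.1) recurred. After shuffling the peaks within their chromosomes these shares were 0.890% ± 0.042 and 0.903% ± 0.042 (SD over 100 shuffles). With both lists cut to peaks with a −log10 q of at least 5, recurrence was 79.3% and 88.6%. A peak whose partner fell under that limit counted there as not recurring, unlike in the shares above.

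**Figure D1:**
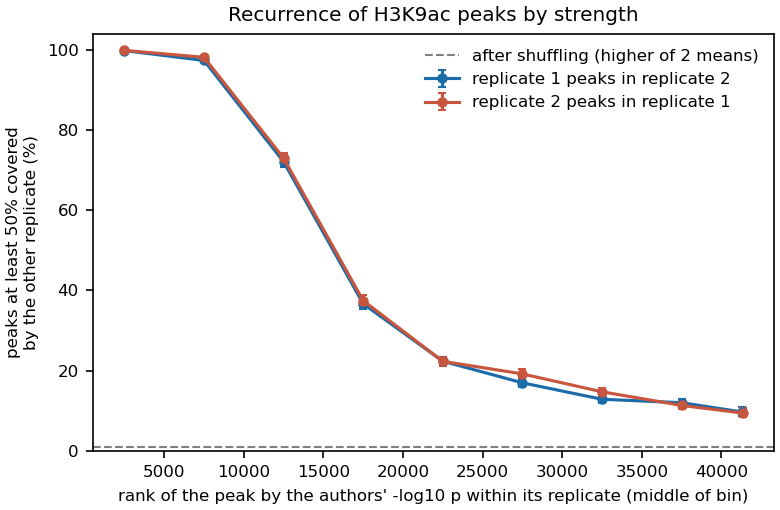
Share of each replicate's H3K9ac peaks (%) with at least 50% of their length covered by the other replicate's peaks, by rank of the peak in its own list; points are bins of up to 5000 peaks with 95% Wilson intervals, and the dashed line is the higher of the 2 shuffled means, 0.903%. Both curves run from at least 99.8% among the 5000 strongest peaks to under 10% beyond rank 40000.

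Actb, which encodes β-actin, ranked highest among promoter peaks, with a mean fold enrichment of 30.5 (geometric mean of 39.3 in replicate 1 and 23.7 in replicate 2) at chromosome 5, 142903753 to 142906801. It was followed by the splicing-factor kinase gene Clk1 (30.0), Bicral (29.2), the circadian clock gene Per1 (28.1) and the small GTPase gene Rac1 (26.3). The next were Top1, which encodes topoisomerase I (25.8), Actg1, which encodes γ-actin (25.7), Zc3h4 (25.5) and the 14-3-3 gene Ywhaz (25.5). The polyubiquitin gene Ubc and the gene model Gm10382 shared 1 peak with a mean of 25.3, and Mgat4b and the autophagy receptor gene Sqstm1 shared another with 24.9. The remaining genes of the 20 strongest were Eif4a2 (24.9), Srsf6 (24.5), Cirbp (24.1), Pnrc1 (24.0), Skp1a (23.9), Pcif1 (23.7) and Ppp4r3b (23.6). Across 19215 pairs of peaks that overlapped best in both lists, log2 fold enrichment correlated with a Spearman coefficient of 0.864 and a Pearson coefficient of 0.881. These correlations are across peaks, which are not independent replicates. Fold enrichment, which is relative to each library's own background and so not on 1 scale, was higher in replicate 1 for 75.4% of pairs, with a median log2 ratio of replicate 2 over replicate 1 of -0.25.

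**Figure D2:**
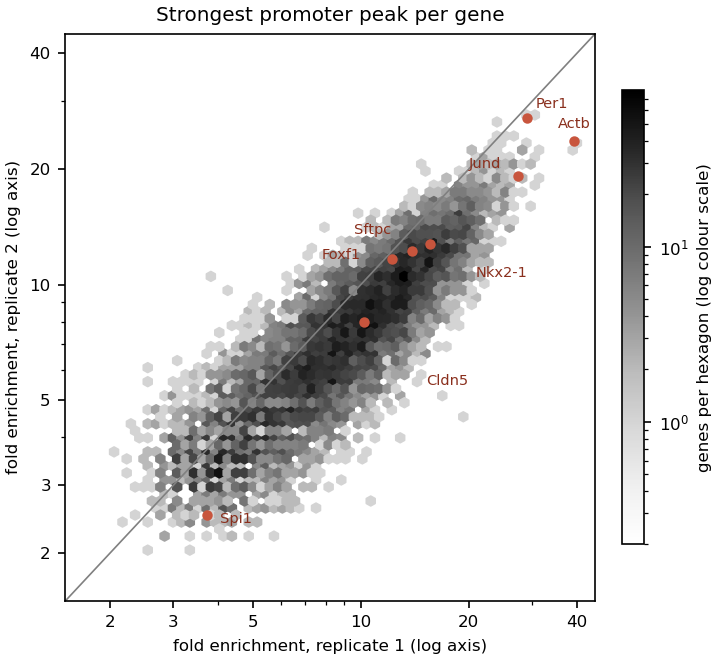
Fold enrichment of the strongest promoter peak of each protein-coding gene in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale), for genes with a replicated promoter peak and a peak in both lists; shading counts genes per hexagon and the line marks equal values. Actb stood at 39.3 and 23.7, Per1 at 29.0 and 27.1, Sftpc at 13.9 and 12.2 and Spi1 at 3.73 and 2.51.

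The replicated list was the strong and wide part of the pooled list. All 19971 replicated peaks were identical to pooled peaks, 44.2% of that list, and they included each of its 5000 strongest. Their median fold enrichment was 5.49 and their median width 870 bp, against 2.60 and 268 bp for the 25176 pooled peaks left out. Each of the 18251 pooled peaks that overlapped a peak of both replicates by at least 50% of either peak was in the list. A further 1720 replicated peaks, with a median fold enrichment of 3.20, did not meet that overlap. Of these, 1639 overlapped a peak in 1 replicate, 54 in both and 27 in none, and the rule by which they were kept is not given in the sources used here. Replicated peaks covered 21.3 Mb, 0.780% of the genome.

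Replicated H3K9ac peaks lay mainly at promoters. Within 1000 bp of an annotated transcript start lay 78.5% of them (interval 77.9 to 79.1), against 6.05% of the genome and 9.36% ± 0.21 after shuffling (SD over 100 shuffles). Exons held 3.30%, introns 10.8% and intergenic sequence 7.40%. Promoter peaks were stronger and wider than the rest, with a median fold enrichment of 6.74 and a median width of 1022 bp, against 3.25 and 492.5 bp in introns. The promoter share was 53.1% in replicate 1 alone, 51.5% in replicate 2 alone and 49.4% in the pooled list, and among pooled peaks outside the replicated list it was 26.4%.

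Of 21911 protein-coding genes, 12355 (56.4%, interval 55.7 to 57.0) had a replicated promoter peak. The share rose with CpG content at the gene's 5′ end, from 17.1% of 8777 CpG-poor genes to 62.9% of 3067 intermediate and 88.7% of 10067 CpG-rich genes. The peak itself could lie at another annotated start. The own list of replicate 1 had a promoter peak at 13085 genes and that of replicate 2 at 12916, with 12307 genes in both. Of the 12355 genes, 204 lacked a promoter peak in at least 1 replicate's own list.

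The T-box gene Tbx2 had the widest replicated domain over a transcript start, with peaks at most 500 bp apart joined, 17067 bp on chromosome 11 from 85829414 to 85846480. Next were Tbx5, a gene of lung mesenchyme and limb (13399 bp), and Foxf1, a forkhead gene of lung mesenchyme and endothelium (12841 bp). Nkx2-1, which encodes the transcription factor that specifies lung epithelium, lay under a single peak of 12450 bp on chromosome 12 from 56525911 to 56538360, the widest peak of the list. In each replicate's own list this stretch was split into several peaks, the strongest with a fold enrichment of 15.6 in replicate 1 and 12.8 in replicate 2. Domains over Tnrc18 (12086 bp), the histone methyltransferase gene Setd1b (10253 bp), Zfp503 (10099 bp) and Irf2bp2 (9388 bp) followed. Those over the kinase gene Sgk1 (8880 bp), the endothelial gene Egfl7 with the overlapping model Gm20532 (8646 bp), Meis2 (8544 bp), Nfib (8514 bp), Tbx3 (8262 bp) and Nr2f2 (8052 bp) completed the widest 15. Over the 11473 protein-coding genes with such a domain the median width was 1569 bp (quartiles 1076 and 2163).

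**Figure D3:**
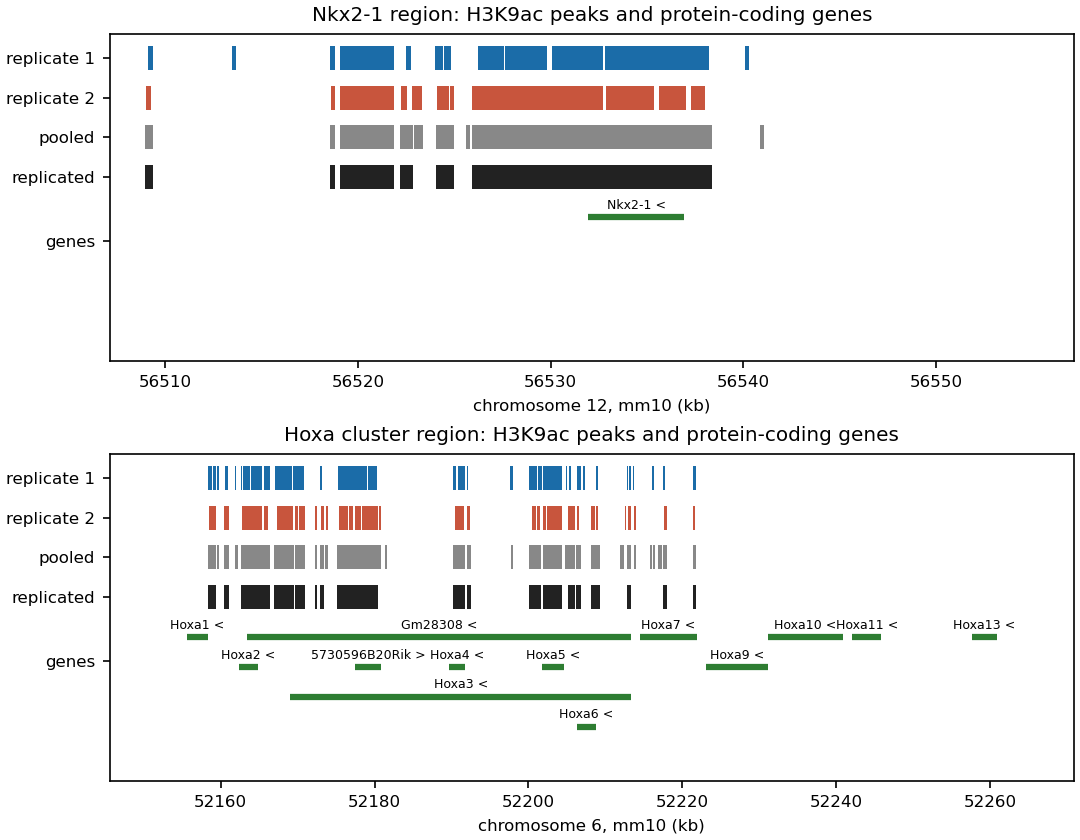
Peaks of the 4 lists (blocks, to scale) and protein-coding genes (green, arrowheads give the strand) over 50000 bp round Nkx2-1 on chromosome 12 and over the Hoxa cluster on chromosome 6, x axis in kb on mm10. One replicated peak of 12450 bp spans Nkx2-1, and the 19 replicated peaks of the Hoxa region lie between positions 52158389 and 52221721, from Hoxa1 to Hoxa7.

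The promoters of genes typical of lung cell types were then compared with all other protein-coding genes by Fisher's exact test, two-sided, adjusted over 38 lists. Lung mesenchyme and fibroblast genes carried the mark at 17 of 18 promoters (exact adjusted p = 0.00148). Their strongest were Foxf1, with a mean fold enrichment of 11.9 (12.2 and 11.7 in replicates 1 and 2), Tbx4 (10.2), Tcf21 (10.1) and Tbx5 (12.5 and 7.98), and Lum, which encodes the collagen-binding proteoglycan lumican, had no replicated peak. Blood vessel endothelium genes carried it at 16 of 18 (exact adjusted p = 0.0111), led after Foxf1 by the TGF-β co-receptor gene Eng (9.81), the tight-junction gene Cldn5 (9.01) and the VEGF receptor gene Kdr (8.96), while Tie1 and Car4 had none. Alveolar type 1 genes carried it at 11 of 12 (exact adjusted p = 0.0243), with Emp2 at 13.3, Gprc5a at 10.98, Lmo7 at 10.05 and Clic5 at 9.60, and Igfbp2 had none. This type 1 call did not pass by permutation against lists matched on promoter CpG class (adjusted p = 0.254) or by the exact test with a −log10 q of at least 5 (0.0567), with the strongest 50% of peaks (0.0713) or with the pooled list (0.0535), and the mesenchyme call did not pass with the strongest 50% of peaks (0.413).

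Genes of alveolar type 2 cells, the cells that make pulmonary surfactant, carried a replicated peak at 10 of 14 promoters. This share did not pass against all other genes (exact adjusted p = 0.349), although 92.9% with the pooled list did (exact adjusted p = 0.0235). Against random lists matched on promoter CpG class, in which 37.5% of members were marked, the 71.4% of type 2 genes passed (permutation test, adjusted p = 0.00718). The surfactant protein C gene Sftpc, whose promoter is CpG-poor, had the strongest, a mean of 13.04 (13.9 and 12.2) over 4515 bp on chromosome 14 from 70518869 to 70523383. Cebpa followed at 9.61, Etv5 at 8.40 and the lipid transporter gene Abca3 at 8.11. Sftpa1, Lamp3 and Il33 had no replicated peak, with 1 peak each in a single replicate. Smooth muscle and pericyte genes were marked at 8 of 12 (exact adjusted p = 0.601, and 0.0460 by permutation against CpG-matched lists, where 36.8% were marked). Pdgfrb, the receptor gene of pericytes, led them at 5.88, Hhip stood at 5.80, Des at 4.77 and Notch3 at 4.49, and Myh11, Cnn1 and Actg2 had none.

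Lung epithelial transcription factors carried the mark at 14 of 17 promoters (exact adjusted p = 0.0638). Foxp1 (16.3), Nkx2-1 (14.1), Foxp4 (9.01) and Gata6 (8.33) were their strongest, and Sox2, Ehf and Etv4 had no replicated peak. This list passed with a −log10 q of at least 5 (exact adjusted p = 0.0361), with a 500-bp promoter window (0.04005), with the pooled list (0.00891) and without replicate 1 (0.0227), but not against CpG-matched lists, where 70.0% were marked (permutation test, 0.399). Ciliated cell genes carried it at 8 of 12 (exact adjusted p = 0.601), with Rfx3 at 11.9, the dynein gene Dnaic1 at 8.10, Cfap126 at 4.67 and Rfx2 at 4.35, and without a replicated peak at Dnah5, Dnah9 and Mcidas. Lymphatic endothelium genes stood at 3 of 7 (exact adjusted p = 0.535), with Nr2f2 at 16.8, Prox1 at 3.72 and a peak of 4.24 at Lyve1 in replicate 1 alone, and Flt4, Ccl21a and Reln had none. Mesothelium genes stood at 3 of 8 (exact adjusted p = 0.355), with Krt19 at 6.98, Upk1b at 4.35 and Msln at 3.30, and Wt1, Upk3b and Lrrn4 had none.

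Genes of 3 lung lists carried the mark less often than other genes. Secretory airway cell genes had 2 of 10 promoters marked (exact adjusted p = 0.0358), Cldn10 at 6.00 and the retinaldehyde dehydrogenase gene Aldh1a1 with a peak of 3.19 in replicate 2 alone, and the secretoglobin genes Scgb1a1, Scgb3a1 and Scgb3a2 had no replicated peak. Neuroendocrine cell genes had 1 of 10 (exact adjusted p = 0.00658), the mechanosensitive channel gene Piezo2 at 7.04, and none at Ascl1, Calca or Chga. Leukocyte genes had 4 of 19 (exact adjusted p = 0.00433), all weak, with Lcp1 at 4.84, Coro1a at 3.15, Fcer1g at 3.07 and the myeloid transcription factor gene Spi1 at 3.06, and none at Ptprc, Csf1r or Cd68. Against CpG-matched lists (permutation test), the secretory and leukocyte shares of 20.0% and 21.1% lay slightly above the expected 17.3% and 19.4% and their calls ended (adjusted p = 1.0 for both), while the neuroendocrine call held (76.0% expected, adjusted p = 0.000844). The secretory and neuroendocrine calls also ended with the strongest 50% of peaks (exact adjusted p = 0.0834 for both), with the pooled list (0.234 for both) and without replicate 1 (0.131 for both).

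All 11 lists of cell types from other tissues or blood carried the mark less often than other genes. No replicated promoter peak was found at 12 liver genes, among them the albumin gene Alb, Afp and Apoa1. The same held for 12 intestine genes (Cdx1, Cdx2, Vil1), 12 pancreas genes (Pdx1, Ptf1a, Ins1) and 12 retina genes (the rhodopsin gene Rho, Crx, Nrl), with an adjusted p of 0.000199 for each of these 4 lists. Vil1 and the retina gene Abca4, the latter chosen after its values were seen, had a peak in each replicate's own list but no replicated peak. Neuron and glia genes had 1 of 14 marked (exact adjusted p = 0.000592), Slc17a7 with a peak of 3.99 in replicate 2 alone, and none at Neurod1, Neurog1 or Neurog2. Kidney genes had 1 of 12 (Wnt9b at 2.83, none at Pax2, Pax8 or Six2) and epidermis genes 1 of 12 (Krt10 at 6.39, none at Krt5, Krt14 or Krt1), each with an adjusted p of 0.00174. Heart muscle genes had 2 of 12 (Ryr2 at 3.90 and Actc1 at 3.30, none at Nkx2-5, Myh6 or Myh7), as had germ line genes (Dazl at 4.98 and Tex14 at 4.91, none at Ddx4, Stra8 or Sycp1). Skeletal muscle genes also had 2 of 12 (Ckm at 4.05, none at Myod1, Myog or Myf5), with an adjusted p of 0.0111 for each of the 3. The other marked skeletal muscle gene was Actn3 (9.76), with a peak on chromosome 19 from 4878640 to 4879516. Erythroid genes had 2 of 11 (exact adjusted p = 0.0204), with Klf1 at 4.91 and Gypa at 3.33, and none at the globin genes Hba-a1, Hba-a2 or Hbb-bs. Of the 11 marked genes, 6 had a replicated domain over 1 of their own transcript starts, while the peaks of Actn3, Ckm, Ryr2, Klf1 and Gypa lay within the promoter window without covering one. Of the 96 marked genes of the lung lists, 79 had such a domain, and Dnaic1 and Krt19 were among those without. Against CpG-matched lists (permutation test) the calls for erythroid (adjusted p = 1.0), heart muscle (0.561), skeletal muscle (0.220), liver (0.314) and epidermis genes (0.846) ended. The erythroid (0.0550) and germ line (0.121) calls also ended with the strongest 50% of peaks, the heart call with a 2.5-kb window (0.174), the kidney and heart calls with the pooled list (0.268 and 0.602), the heart, skeletal muscle and kidney calls without replicate 1 (0.297, 0.0510 and 0.0510) and the heart call without replicate 2 (0.106).

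Set against each other, the 12 lung lists had 96 of 156 genes marked (61.5%, interval 53.7 to 68.8) and the 11 other cell type lists 11 of 133 (8.27%, interval 4.68 to 14.2), an odds ratio of 17.7 (Fisher's exact test, two-sided, p = 1.65e-22). Among genes CpG-poor at the 5′ end, 37 of 75 lung genes (49.3%) and 5 of 87 other genes (5.75%) were marked at any start, an odds ratio of 16.0 (exact p = 1.25e-10). The odds ratio within CpG-poor promoters was 39.2 with a 500-bp window, 6.81 with the pooled list, 7 with the strongest 50% of peaks, 6.17 without replicate 1 and 6.64 without replicate 2. Over all promoters it was 11.01 with the pooled list, 9.79 without replicate 1 and 10.4 without replicate 2, and each of these tests passed.

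**Figure D4:**
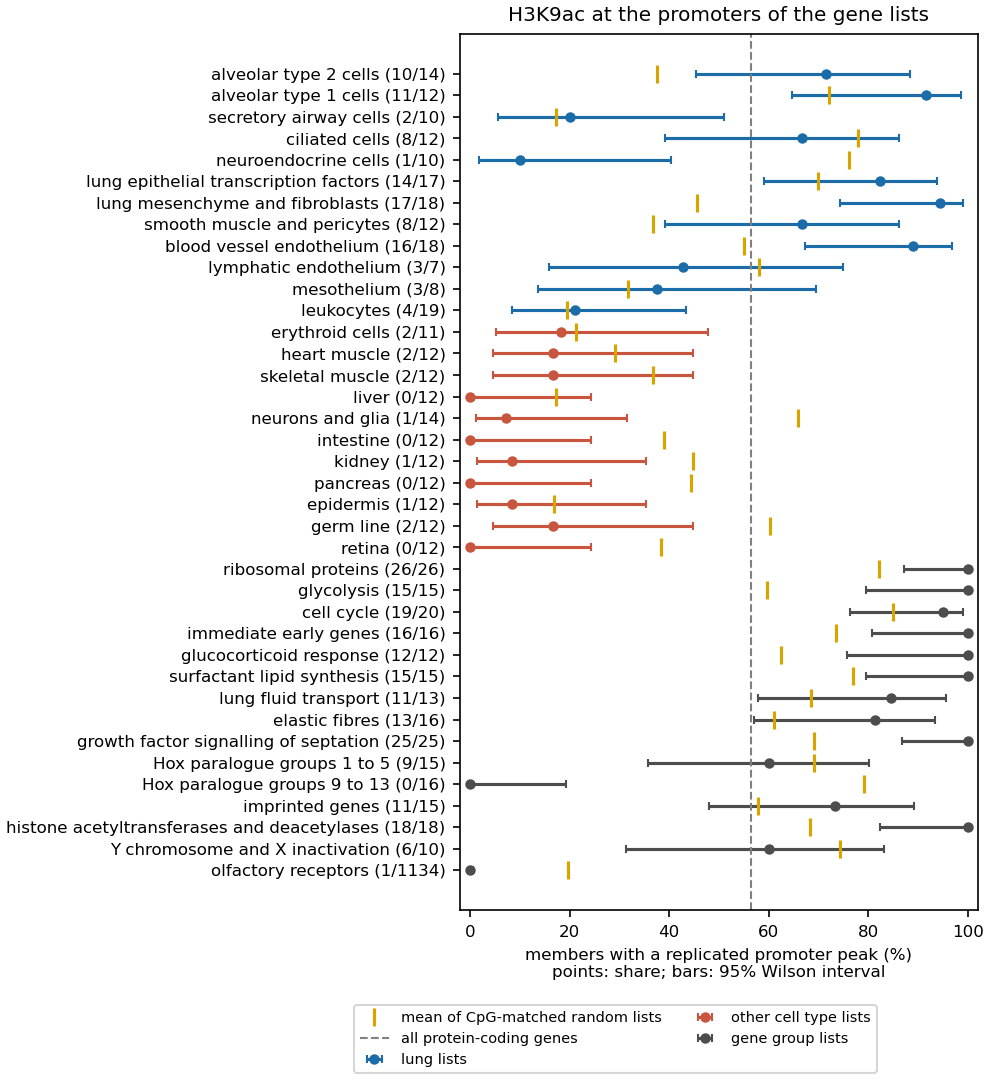
Share of the members of each of the 38 gene lists with a replicated promoter peak (%, points with 95% Wilson intervals; marked and total members in brackets), the mean share in random lists matched on promoter CpG class (upright strokes) and the share of all protein-coding genes (dashed line, 56.4%). The 11 other cell type lists lie between 0 and 18.2%, while lung mesenchyme, alveolar type 1 and vessel endothelium genes lie at 94.4%, 91.7% and 88.9%.

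Among gene groups, several were marked at every member, as were the ribosomal protein and glycolysis genes described below. With no other tissue or age in the series, these marks cannot be tied to the perinatal lung. Genes for surfactant lipid synthesis were marked at 15 of 15 promoters (exact adjusted p = 0.000772), led by the phospholipid synthesis genes Cept1 (13.4) and Chka (12.8), Pnpla8 (9.52) and Elovl1 (9.10). Growth factor genes of alveolar septation were marked at 25 of 25 (exact adjusted p = 1.41e-05), with Tgfbr2 at 18.2, Vegfa at 15.8, Bmpr1a at 15.0 and Notch2 at 14.5. Glucocorticoid response genes were marked at 12 of 12 (exact adjusted p = 0.00382) and immediate early genes, which respond within minutes to stimuli, at 16 of 16 (exact adjusted p = 0.000536). The first group was led by Per1 (28.1), Klf9 (20.9), Cebpd (18.0) and Errfi1 (16.5), the second by Jund (22.9), Dusp1 (21.1), Jun (19.2) and Btg2 (18.9). Histone acetyltransferase and deacetylase genes were marked at 18 of 18 (exact adjusted p = 0.000199), with the acetyltransferase genes Ep300 at 21.9, Crebbp at 19.7, Kat7 at 15.8 and Kat6b at 13.96. For the groups from surfactant lipid synthesis to histone acetyltransferases and deacetylases, CpG-matched random lists had from 62.4% (glucocorticoid response) to 76.9% (surfactant lipid synthesis) of members marked. Each of these groups passed against such lists by permutation. Lung fluid transport genes were marked at 11 of 13 (exact adjusted p = 0.0647), with the Na,K-ATPase genes Atp1b1 (12.9) and Atp1a1 (11.3), the epithelial sodium channel gene Scnn1a (10.1) and Slc12a2 (8.96), and no replicated peak at Aqp3 or Aqp4. This list passed with a −log10 q of at least 5 (exact adjusted p = 0.0368), with the gene 5′ end alone (0.0366) and without replicate 1 (0.0318), but not against CpG-matched lists, where 68.4% were marked (permutation test, 0.312). Elastic fibre genes were marked at 13 of 16 (exact adjusted p = 0.0938), with Fbn1 at 7.76, the elastin gene Eln at 7.68, Lox at 7.64 and Efemp2 at 7.21, and none at Loxl2, Fbln2 or Mfap5, and they passed without replicate 2 (0.0330) but not against CpG-matched lists (permutation test, 0.149).

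Groups used by most cells were marked at nearly all members. Ribosomal protein genes were marked at 26 of 26 (exact adjusted p = 1.10e-05; Rps6 18.5, Rps19 18.1, Rps27 17.7, Rpl11 17.3) and glycolysis genes at 15 of 15 (exact adjusted p = 0.000772), with Ldha at 11.2, Pfkm at 10.5, Aldoa at 9.48 and Eno1 at 8.56. Cell cycle genes were marked at 19 of 20 (exact adjusted p = 0.000939), with the mitotic kinase gene Aurka at 13.4, the replication helicase genes Mcm4 at 7.65, Mcm5 at 6.00 and Mcm7 at 5.70, and none at Ccnb2. With the strongest 50% of peaks the glycolysis (exact adjusted p = 0.168) and cell cycle (0.691) calls ended, and against CpG-matched lists the cell cycle call did (0.428). Of the Hox genes, 0 of 16 of paralogue groups 9 to 13 were marked (exact adjusted p = 1.62e-05, Hoxa9, Hoxa10 and Hoxa11 among them) and 9 of 15 of groups 1 to 5 (exact adjusted p = 1.0). Each list was tested against all other genes, and the anterior and posterior lists were not tested against each other. The marked anterior genes were in the Hoxa and Hoxb clusters, with Hoxa5 at 12.5, Hoxb5 at 9.82, Hoxa4 at 9.76 and Hoxb3 at 9.55, while Hoxb1, Hoxc4 and Hoxc5 had none. A split between anterior and posterior genes was thus seen in the Hoxa and Hoxb clusters only. Imprinted genes were marked at 11 of 15 (exact adjusted p = 0.252; Grb10 9.73, Igf2r 8.40, Impact 7.17, Peg10 6.91), with none at Snrpn, Ndn or the untested non-coding H19. Protein-coding genes of the Y chromosome and X inactivation list were marked at 6 of 10 (exact adjusted p = 1.0; Ddx3x 20.1, Kdm5c 14.3, Kdm6a 9.92, Ddx3y 4.46), with none at Eif2s3y, Zfy1 or the untested Tsix. Olfactory receptor genes had 1 of 1134 marked, Olfr56 at 3.75, against 59.5% of other genes and 19.7% in CpG-matched lists (permutation test, adjusted p = 0.000844, from the smallest p these permutations can give). Altogether 11 lists lay above other genes and 16 below, and against CpG-matched lists 11 lay above, 9 of them the same lists, and 9 below, all among the 16.

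Promoter strength set some of these groups apart. In each case the median over a list's marked members was placed among 10000 random lists of marked genes of the same CpG classes. Ribosomal protein genes (median fold enrichment 13.9, above all random lists), glucocorticoid response genes (15.1, above all), immediate early genes (13.4, percentile 99.99) and histone acetyltransferase and deacetylase genes (10.8, percentile 99.86) lay in the top 2.5%. Leukocyte genes (3.11, percentile 0.05), cell cycle genes (5.14, percentile 0.06) and ciliated cell genes (4.67, percentile 1.64) lay in the bottom 2.5%, and only 1 list did so with a −log10 q of at least 5 or with the strongest 50% of peaks. The other 15 lists with at least 3 members that had a fold enrichment in both replicates lay between, and lymphatic endothelium genes were too few to be placed. The log2 ratio of promoter fold enrichment in replicate 2 over replicate 1 had a median of -0.31 over 12151 genes, and relative to random lists of like strength 2 lists lay outside the central 95%, where 1.1 of 22 would by chance. These were ribosomal protein genes (-0.50, percentile 0.58) and lung epithelial transcription factors (-0.53, percentile 1.34), both lower in replicate 2, with 1 library on each side.

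Distal peaks, over 5000 bp from any transcript start, numbered 2113, or 10.6% of replicated peaks on placed chromosomes. Within 1000 bp of a transcript start in the RefSeq annotation lay 219 of them (10.4%, against 1.28% after shuffling), 22 of the 100 strongest among these, and 53 of the 100 strongest had an observed over expected CpG over 0.6. They were weaker than the rest, with a median fold enrichment of 3.41 against 6.02. Immediate early genes had the most within 50000 bp, 1.19 ± 1.42 per gene (SD, 16 genes) with at least 1 near 10 of them, against 0.170 in random lists (permutation test, two-sided, adjusted p = 0.00380 over 38 lists). Septation growth factor genes had 0.72 ± 1.06 per gene (SD, 25 genes), near 10 genes, against 0.172 (permutation test, adjusted p = 0.0127), a call that ended with a −log10 q of at least 5 (0.410) and with the strongest 50% of peaks (1.0). Olfactory receptor genes had 0.0238, against 0.178 (permutation test, adjusted p = 0.00380). The unadjusted p of the first and last, 0.0002, is the smallest these permutations can give. Lung epithelial transcription factors had 0.706 (permutation test, adjusted p = 0.0817), glucocorticoid response and mesenchyme genes 0.667 and 0.556 (adjusted p = 0.196 for both) and retina genes 0.583 (0.293), and no other list passed. Alveolar type 1 genes, at 0.50 (adjusted p = 0.446 by permutation), passed with the pooled list (3.83 per gene, 0.00380), without replicate 1 (3.17, 0.00760) and without replicate 2 (3, 0.00380). Single replicates also passed by permutation for glucocorticoid response genes (2.83 per gene without replicate 2, adjusted p = 0.00912), surfactant lipid synthesis genes (2.27 without replicate 2, 0.0190) and elastic fibre genes (2.19 without replicate 1, 0.0355). The pooled and single-replicate lists hold 42571 to 45147 peaks, against 19971 replicated ones, so random lists have more distal peaks there too. Counts per gene from these lists cannot be set against those of the replicated list. Posterior Hox genes were lower, at 0 without replicate 1 (permutation test, adjusted p = 0.00380) and 0.0625 without replicate 2 (0.0271). Hox and olfactory receptor genes lie in clusters, so neighbouring members share much of their windows of 50000 bp, unlike scattered random genes. The permutation p of these lists treats members as separate loci and is too small.

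The strongest distal peak, with fold enrichments of 14.4 and 12.2 in replicates 1 and 2, lay in intergenic sequence on chromosome 12 from 70967923 to 70969196, 5425 bp from the proteasome gene Psma3. The second lay 32403 bp from Pum2 on the same chromosome, from 8640748 to 8641731 (12.6 and 11.2), and the third on chromosome 15 from 85669726 to 85673388 (14.9 and 13.3), in an intron 16110 bp from a start of the non-coding gene Lncppara. The others of the strongest 10 lay nearest to Gm44738 (7975 bp), Nrg2 (12918 bp, in an exon), Zfp869 (5402 bp), the Polycomb gene Cbx8 (15291 bp), Gm5218 (22738 bp), Tmem44 (29282 bp) and Sorbs3 (11705 bp, in an exon).

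Of 22 transcription factor consensus sequences, 2 were more frequent in 1-kb windows at 1610 distal peaks than in as many GC-matched control windows. The forkhead (FOXA) consensus occurred in 28.3% of peak windows and 18.9% of controls, an odds ratio of 1.69 (Fisher's exact test, two-sided, adjusted p = 9.76e-09). The CTCF consensus occurred in 3.23% and 1.12%, an odds ratio of 2.95 (exact adjusted p = 0.000536). The forkhead difference was lost without GC matching (odds ratio 1.06, exact adjusted p = 0.546), and only its call was lost in the strongest 50% of peaks (1.64, adjusted p = 0.955). The CTCF call, but not the ratio, was lost among the strongest 50% of peaks (6.41, exact adjusted p = 0.955) and with windows of 250 bp either side (2.81, exact adjusted p = 0.0954), and its odds ratio fell to 1.70 without replicate 1 and 1.69 without replicate 2, where it passed. None of 100 scrambled forkhead sequences reached its odds ratio, the highest being 1.65, whereas 6 of the 63 scrambled CTCF sequences with a ratio did. The NKX2-1 consensus occurred in 36.6% and 32.4% (exact adjusted p = 0.106) and passed with the pooled list (odds ratio 1.08, adjusted p = 0.0142) and in each replicate alone (1.07 and 1.13, adjusted p = 0.0280 and 0.000230). Without distal peaks near RefSeq starts, NKX2-1 (odds ratio 1.25, exact adjusted p = 0.0284) and RUNX (1.59, 0.0146) passed as well. Single replicates brought further calls, 9 sequences above controls and 2 below without replicate 1, and 5 above and 1 below without replicate 2. The PU.1 (exact adjusted p = 0.121) and MYOD E-box (0.145) sequences had an unadjusted p under 0.05 as well, HNF1 and PAX6 sequences were in no window, and 0 sequences were rarer in peaks by Fisher's exact test, adjusted or at an unadjusted p under 0.05.

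**Figure D5:**
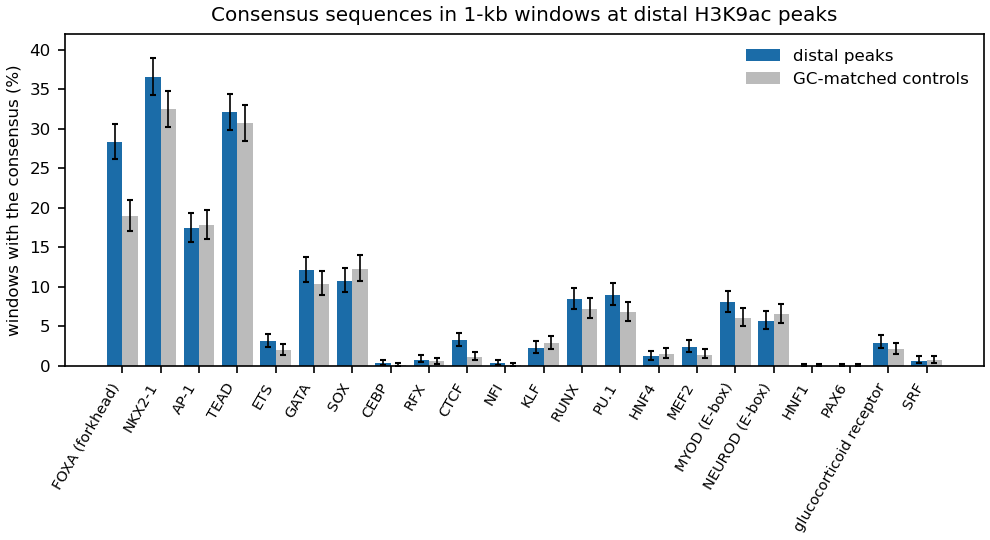
Share of 1-kb windows (%) with each of 22 consensus sequences at 1610 distal H3K9ac peaks and in as many GC-matched control windows (bars from 0, with 95% Wilson intervals). The forkhead consensus stands at 28.3% in peaks and 18.9% in controls and CTCF at 3.23% and 1.12%, while the intervals of the other pairs overlap.

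Promoters with a peak in the own list of 1 replicate only had weak peaks. These were 778 genes in replicate 1 and 609 in replicate 2, of which 120 and 79 nevertheless had a replicated promoter peak, with median fold enrichments of 3.39 and 3.16 against 8.82 and 7.18 for genes with a peak in both. Of the 10 genes named here, all but Ushbp1 had a replicated promoter peak. The strongest in replicate 1 were Rnf151 (13.6) and Nanos3 (13.2), whose peaks lay 939 and 689 bp from the gene's start and overlapped a peak of replicate 2 that fell outside the promoter window. Fam234a (7.84), Prkg2 (7.12) and Proca1 (7.12) followed, each with a peak over its own start and no overlapping peak in replicate 2. In replicate 2 the peaks assigned to Hyal1 (10.4) and Ushbp1 (6.14) covered the starts of the neighbours Hyal3 and Babam1 and overlapped a peak of replicate 1. Rspo3, which encodes a Wnt pathway agonist (5.33), Adra1b (5.32) and Pfkfb4 (5.08) had no overlapping peak in replicate 1. Of the 778 and 609 genes, 773 and 605 had no overlapping peak in the other replicate.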

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

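Leaving out distal peaks near RefSeq starts and keeping only peaks that overlap both replicates by 50% were the alternatives chosen after the data had been seen. The lung against other cell type comparison kept its direction and passed under all 9 alternatives run, with odds ratios from 9.79 to 24.3 over all promoters and from 6.17 to 39.2 in CpG-poor promoters. Of the shares of list members with a promoter peak under alternatives, 301 kept direction and side of the threshold, 28 no longer passed, 11 newly passed and 2 reversed, the secretory (20.0%) and leukocyte (21.1%) shares against CpG-matched lists, which expect 17.3% and 19.4%. For distal peaks near lists, 251 kept their side, 13 newly passed and 2 no longer did, and for consensus sequences 111, 19 and 4. Settings in which a sequence was missing from the peaks or the controls gave no ratio and were left out.

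With a −log10 q of at least 5, recurrence was 79.3% for replicate 1 and 88.6% for replicate 2, the Spearman and Pearson coefficients 0.807 and 0.817, the promoter share 87.2%, marked genes 53.7%, lists weak in strength 1, genes marked in replicate 2 alone 350 and lists with more distal peaks 1. With the strongest 50% of peaks, recurrence was 66.5% and 67.7%, the coefficients 0.849 and 0.857, replicated peaks 9983, the promoter share 96.5%, marked genes 43.7%, lists above other genes 7, lists weak in strength 1, lists with more distal peaks 1 and sequences above controls 1. That sequence was neither the forkhead nor the CTCF consensus, whose calls were lost there. Recurrence was 50.5% and 50.7% with 1 bp of overlap and 30.9% and 32.85% with 80% overlap. It was 69.7% and 71.1% when both lists were cut to their 20000 strongest peaks. The −log10 q limit and the strongest 50% of peaks likewise cut both lists, so a partner outside the cut did not count. The coefficients were 0.873 and 0.884 with −log10 p as strength. A looser or stricter overlap moves recurrence by construction; for the other values the cause was not tested.

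The promoter share was 74.9% with a window of 500 bp and 84.9% with 2.5 kb. Marked genes were 57.2% with 2.5 kb and 52.8% with the gene 5′ end alone. With the pooled list the promoter share was 49.4%, marked genes 61.6%, lists above and below random in distal peaks 4 and 4, and sequences above controls 6. Without 1 replicate the promoter share ranged from 51.5% to 53.1%, marked genes from 58.9% to 59.7%, lists above random in distal peaks from 4 to 5 and below from 2 to 2, sequences above controls from 5 to 9 and below from 1 to 2. With CpG-matched lists 9 lists lay below. Windows of 250 bp left 1 sequence above controls, controls without GC matching gave 1 below, and leaving out distal peaks near RefSeq starts gave 4 above. The cause was not tested. Without read counts, how far depth limits the weak peaks is unknown.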

Other observations

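The widths of list domains, the counts by chromosome and gene type, the shift by strength, the steps in fold enrichment and both tests of non-recurring peaks were chosen after the results were seen, as was the CpG-matched test of domain width. With 1 group, no biological explanation was tested.

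Genes of the X chromosome were marked less often than autosomal genes, at 315 of 948 (33.2%) against 12037 of 20780 (57.9%), an odds ratio of 0.361 (Fisher's exact test, two-sided, p = 1.30e-50). Among CpG-rich promoters the shares were 69.0% and 89.2% (odds ratio 0.269, exact p = 7.78e-18), and the median fold enrichment of marked genes over all promoters was 5.27 and 8.10. Both pools held males and females, and the number of X chromosomes per cell was not accounted for. Of non-coding genes over 5000 bp from any protein-coding start, 236 of 5134 lincRNA genes (4.60%), 52 of 1338 antisense genes (3.89%), 70 of 358 processed transcript genes (19.6%) and 29 of 8910 processed pseudogenes (0.325%) had a replicated promoter peak. Malat1, a nuclear RNA gene, had fold enrichments of 16.4 and 16.0 in replicates 1 and 2, and Neat1, the paraspeckle RNA gene, 17.2 and 16.2, both named after their values were seen.

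Fold enrichments lay on a regular grid within 0.0005 for 56.5% of replicate 1 peaks (step 0.339, 0.295% by chance), 58.5% of replicate 2 peaks (0.266, 0.376%) and 58.9% of pooled peaks (0.163, 0.615%). The median log2 ratio of promoter fold enrichment in replicate 2 over replicate 1 went from -0.20 in the 1216 genes with the weakest promoters to -0.35 in the 1214 with the strongest, and it was under 0 in all 22 lists. Explanations of this shift were examined and are not weighed here.

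More than 50% of each replicate's peaks did not recur in the other at 50% overlap, while with 1 bp of overlap 50.5% and 50.7% recurred. With both lists cut to a −log10 q of at least 5, 79.3% and 88.6% recurred at 50% overlap. Calls at random places of the genome are argued against as the only source. Peaks without any overlap lay at promoters in 25.2% (replicate 1) and 21.6% (replicate 2) of cases, against 7.15% and 7.25% after shuffling, a smallest excess of 14.3 percentage points. A mixture of random calls with a smaller part of promoter peaks would give such values too. The shuffle also does not model uneven background, so the share of random calls is unknown. A position near the calling threshold may account for part of it, as recurrence fell to at most 9.70% beyond rank 40000. Those ranks held only 2566 and 2688 peaks of replicates 1 and 2. At ranks 15001 to 20000 recurrence was already 36.7% and 37.4%. The median −log10 p there was 5.98 and 5.57, while the lowest deposited value was 2.00. Much of the loss thus lay above that floor, and its cause was not settled. Differences between the pools of mice stay open.

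The forkhead consensus was more frequent in distal peaks than in GC-matched controls (odds ratio 1.69, interval 1.43 to 1.99). Promoters missing from the annotation but listed in RefSeq were not the whole cause. Without the 219 distal peaks near RefSeq starts the ratio was 1.63 (interval 1.37 to 1.93, exact adjusted p = 5.32e-07). Only 10.4% of distal peaks were left out, so the ratio could move little. Starts absent from both annotations were not covered, and 325 distal peaks had an observed over expected CpG over 0.6. Missing promoters in general thus stay open. Of 100 scrambled sequences, 0 reached the observed ratio, but the highest, 1.65, lies inside its interval, so base composition beyond GC content cannot be told apart, and without GC matching the ratio was 1.06. Both limits were tightened after the values were seen, to require the interval's lower bound over 1.3 and over every scrambled ratio, which moved the second verdict from excluded to open.

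Lung epithelial transcription factor genes carried wide domains, with a median of 2600 bp over 13 genes, and were singled out after the widest domains were seen. Random lists matched on promoter CpG content, promoter peak strength or number of annotated transcript starts had medians of 1481, 1474 and 1564 bp, which placed the list at percentiles 99.95, 100 and 99.94. None of these 3 explanations is thereby enough alone, and what sets the width was left open. Wide domains were not particular to this list, since 12 of 22 lists lay in the top 2.5% of random lists, among them immediate early genes (5135 bp), lung fluid transport genes (4083 bp) and alveolar type 2 genes (3633 bp), while ciliated (781 bp) and smooth muscle genes (818.5 bp) lay in the bottom 2.5%. These lists were matched on CpG class alone.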
